A study of Mus musculus with 14 samples.

How the data were processed

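RNA was measured by poly-A selected RNA-seq in 14 mouse hearts. The mice were male C57BL/6 animals carrying the αMHC-MerCreMer transgene, a tamoxifen-activated Cre recombinase driven by the cardiomyocyte Myh6 promoter. Knockout animals (cKO) also carried floxed Fam210a alleles, and controls carried the transgene without them. Hearts were taken about 5 weeks (early) or about 10 weeks (late) after tamoxifen. Per the labels' protocols, mRNA was purified from 100 ng of total RNA, libraries were made with the TruSeq RNA kit V2, which does not mark the strand, and single-end reads of 100 nt were generated. Per the submitters' processing notes, the tools included Trimmomatic 0.36 and STAR 2.6.0c and the genome build was GRCm38. The counting tool, its annotation and its strand setting are not given in the sources used here.

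The deposited values are whole-number read counts per gene symbol, not normalized by the authors as far as the values show, in 1 table per time point with the same 53735 symbols. Totals were 15657298 to 19466469 counts in the 8 early hearts and 29989076 to 35750964 in the 6 late hearts. Each time point is its own table, so time and table cannot be told apart, and levels were not compared between times. Only the change within a table was compared. Of the symbols, 28535 (53.1%) were found in GENCODE M21, from which coordinates on GRCm38 were taken. The chi-square per gene between hearts of the same group was 3.90 or more, so no library was a copy of another of its group within sampling noise. The labels describe hearts and do not say that every library is a separate animal, so p-values measure the spread between these samples.

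Early cKO replicate 4 is a knockout by its title and description, while its genotype field gives the control genotype. It was treated as a knockout, and leaving it out or counting it as a control were alternatives. Samples were otherwise grouped by their labels.

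Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment, and genes were called at an adjusted p under 0.05. Each time point was fitted alone, 4 against 4 early and 3 against 3 late. The difference between times was the genotype-by-time contrast in a fit of all 14 libraries. CPM values were computed here from the deposited counts with the TMM-scaled library sizes. Standard errors are the log2 fold change divided by the square root of F. Unless another tool is named, an adjusted p below is from this edgeR test.

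Before the data were examined, 38 gene lists were fixed, covering stress responses, metabolism, contraction, matrix and the cell types a heart can hold. Lists with at least 5 tested members, 36 early and 38 late, were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. That form of camera gave much larger p-values even where the estimate equalled the preset 0.01, as for late interferon genes. Its p-values are therefore not a measure of gene correlation alone. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes. Single values were compared with exact two-sided permutation tests. With 3 against 3 hearts the smallest such p is 0.1, and with 4 against 4 it is 0.0286.

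The named genes were also chosen by a rule fixed before the data were examined. They are Fam210a, then the 10 largest rises and 10 largest falls among called genes with an average log2 CPM of at least 1 and no overlap between the groups, leaving out predicted genes, pseudogenes and Y-linked genes or Xist. Up to 4 members with the smallest p were taken from each described list, and the 5 largest differences in each direction between times. Of the genes selected by this rule, 1 is not reported here. For a gene with no count in any library of a group, a fold was computed against a floor of 3 counts over the group. With 1 to 3 counts it is given with a 95% exact counting interval. Reads are not separate molecules, so intervals and floors cover counting error only.

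The procedure was tested on simulated counts with 200 changed genes, all above a minimum expected count. Each gene was drawn independently, so no simulated heart stood apart as a whole, and the shares need not hold for the real hearts. At the early depth and group size, 80% of 1.5-fold and 100% of 3-fold changes were recovered over 13387 tested genes, and 6.6% of calls were on unchanged genes. For the late design these values were 16%, 96% and 3.4% over 14441 genes, and for the difference between times 14%, 90% and 4.6% over 14116 genes. Fold changes were checked against transcript length and GC content for 90.3% of early and 87.3% of late genes. Spearman correlations across genes, which are not independent replicates, were 0.002 with length and 0.038 with GC early, and -0.011 and -0.037 late. With mean expression they were larger, at -0.158 early and 0.289 late. Alternatives covered size factors, library sizes without mitochondrial genes, other low-count filters, DESeq2 1.42.0, limma-voom, each replicate left out, a replicate block, the label of early cKO replicate 4 and a joint fit. After seeing the data, leaving out the libraries with the most atrial transcripts was added.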

Results

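Gene expression was measured in the hearts of mice that lost Fam210a in cardiomyocytes after tamoxifen and of control mice with the same inducible Cre. Fam210a encodes a mitochondrial protein. Hearts were taken about 5 weeks after tamoxifen, when cardiac function was described as normal, with 4 cKO and 4 control hearts. Other hearts were taken about 10 weeks after tamoxifen, when function was described as strongly impaired, with 3 cKO and 3 control hearts. Early libraries held 15657298 to 19466469 counts and late libraries 29989076 to 35750964.

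The targeted gene was examined first. Fam210a lies on chromosome 18 from 68260187 to 68300333 on the minus strand (GRCm38). It overlaps Ldlrad4 on the other strand, so reads in the shared stretch cannot be assigned to 1 gene without strand information. Early, Fam210a stood at 146 ± 10.2 CPM in cKO hearts and 170 ± 6.04 CPM in controls (SD, n = 4 each). The log2 fold change was -0.22 with an SE of 0.06 and did not pass edgeR's test across all genes (adjusted p = 0.17), although every cKO heart was below every control (exact permutation p = 0.0286, the smallest possible). Late, it fell from 128 ± 7.27 to 66.8 ± 3.41 CPM (SD, n = 3 each; log2 fold change -0.94, SE 0.11, edgeR adjusted p = 6.5e-05). Late, Ldlrad4 also fell by 0.91 on the log2 scale (SE 0.22, adjusted p = 0.00563), so the late size for Fam210a is uncertain. The neighbouring gene Rnmt, which starts at 68300355 and does not overlap Fam210a, rose by 1.06 (SE 0.11, adjusted p = 3.79e-05). The part of Fam210a that was deleted and its level in single cell types were not analysed here.

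**Figure D1:**
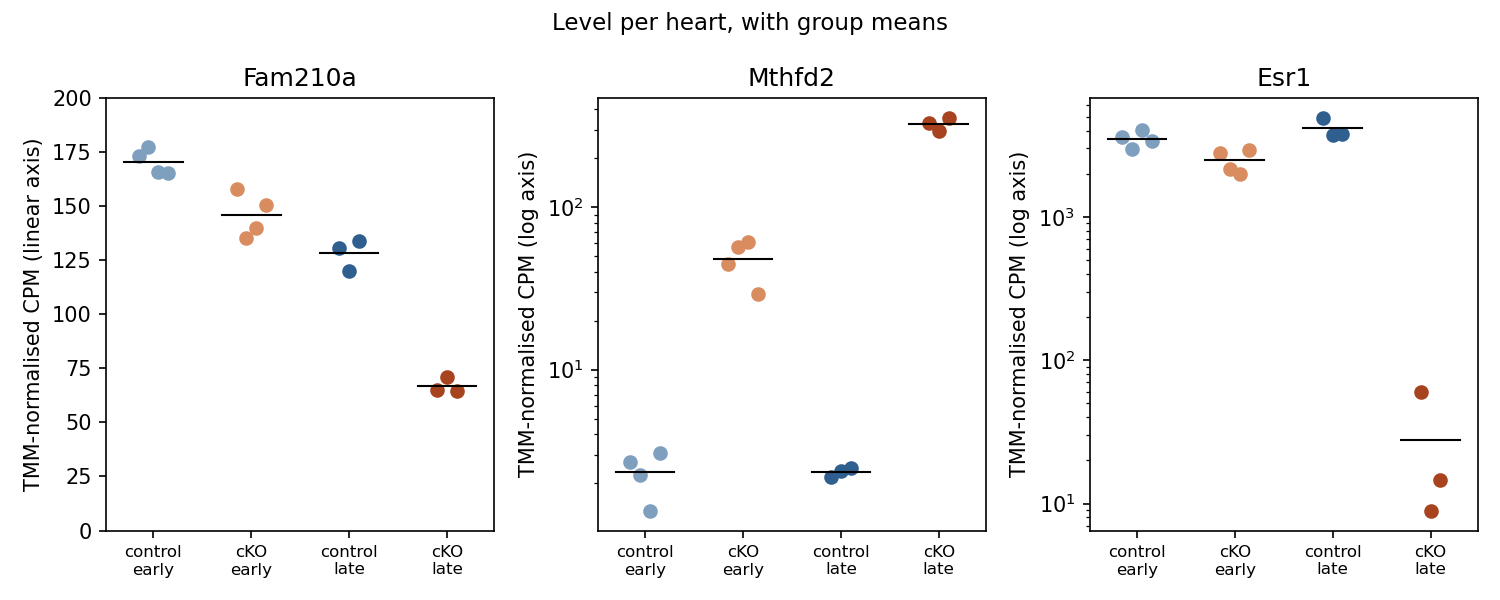
Levels of Fam210a (linear axis), Mthfd2 and Esr1 (log axes) in TMM-normalised CPM, with each point a heart and each line a group mean (4 hearts per early group, 3 per late group). Early cKO hearts held 29.2 to 60.8 CPM of Mthfd2 against 1.35 to 3.08 CPM in early controls, and late cKO hearts held 8.90 to 60.1 CPM of Esr1 against 3750 CPM or more in late controls.

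The early comparison asks what changed in knockout hearts while function was still normal. Many of the largest rises were in enzymes that make serine, folate-bound carbon units and proline, and in targets of ATF4. ATF4 is the transcription factor of the integrated stress response. Car3, described below, rose by 3.17 on the log2 scale, more than any gene given here except Mthfd2. Mthfd2, a mitochondrial folate enzyme, rose 20.3-fold from 2.34 ± 0.747 to 47.9 ± 14.3 CPM (SD, n = 4; log2 fold change 4.35, SE 0.26, adjusted p = 9.04e-06). Asns, which makes asparagine, rose 8.51-fold (adjusted p = 8.41e-05), and the proline enzyme Pycr1 rose 4.14-fold (adjusted p = 0.00646). The serine enzymes Phgdh and Psat1 rose 4.04-fold (adjusted p = 0.00358) and 4.03-fold (adjusted p = 0.00106). Gdf15, a secreted stress cytokine, rose 6.54-fold (adjusted p = 0.0126). The amino acid transporter gene Slc7a5 rose 3.91-fold (adjusted p = 0.00164), the lectin Lgals3 3.90-fold (adjusted p = 0.0121) and the adhesion protein Tenm4 3.91-fold (adjusted p = 0.0223). Mthfd2 lies on chromosome 6 from 83305691 to 83325908 and Asns on chromosome 6 from 7675169 to 7693254. Leaving out 1 heart ended the calls of Gdf15 (without control replicate 2 or 3), Lgals3 (without control replicate 3 or 4) and Tenm4 (without cKO replicate 2 or 3 or control replicate 1, 2 or 3), with adjusted p from 0.0505 to 0.0956.

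Of 26 tested ATF4 target genes, 10 rose early and none fell past the test over all genes, and 16 rose and 1 fell when adjusted over the list alone. Atf5 rose from 38.5 ± 3.87 to 135 ± 26 CPM (log2 fold change 1.82, SE 0.12, adjusted p = 2.08e-05) and Atf4 itself by 0.64 on the log2 scale (SE 0.08, adjusted p = 0.00495). The list was higher by camera (adjusted p = 2.79e-13), with adjusted p = 0.155 with an estimated correlation. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, 9 rose and none fell, 11 rose when adjusted over the list alone, and adjusted p = 0.252 with an estimated correlation. Mars rose by 0.73 (SE 0.08, adjusted p = 0.00106) and Iars by 0.54 (SE 0.07, adjusted p = 0.00358) on the log2 scale. Of 14 genes of serine, folate and proline synthesis, 6 rose and none fell, 9 rose when adjusted over the list alone, and adjusted p = 0.135 with an estimated correlation. Camera with the preset correlation gave an adjusted p of 2.79e-13 for the synthetase list and 2.79e-13 for the serine, folate and proline list. By fry the adjusted p was 0.00792 for ATF4 targets, 0.0126 for synthetases and 0.004 for serine, folate and proline genes. Aldh18a1 rose by 1.39 (SE 0.12, adjusted p = 0.000152) on the log2 scale, and Aldh1l2 rose 2.38-fold (adjusted p = 0.00171).

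The falls early were fewer and smaller. Timp4, an inhibitor of matrix proteases, fell from 37.6 ± 4.07 to 19.6 ± 5.61 CPM (SD, n = 4; log2 fold change -0.93, SE 0.17, adjusted p = 0.0237). Banp (log2 fold change -0.91, adjusted p = 0.00358), Mcf2l (-0.78, adjusted p = 0.0133) and Rin3 (-0.61, adjusted p = 0.0285) also fell. Ppargc1a, a coactivator of mitochondrial biogenesis, fell by 0.58 on the log2 scale (adjusted p = 0.0223), Alas1, which starts heme synthesis, by 0.50 (adjusted p = 0.012) and the transcription factor Sox7 by 0.56 (adjusted p = 0.0322). Slc16a7 fell by 0.60 (adjusted p = 0.0314) and Cep128 by 0.56 (adjusted p = 0.0324). The mitochondrial tRNA gene mt-Tw fell from 50.3 ± 6.41 to 31.4 ± 1.52 CPM (adjusted p = 0.00358). The calls of Timp4, Mcf2l, Rin3, Ppargc1a, Sox7, Slc16a7 and Cep128 were each lost without 1 or more single hearts, which were cKO replicates 1, 2 and 3 and control replicates 1, 2, 3 and 4. Their adjusted p was then 0.0504 to 0.121.

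Respiratory chain subunits showed no single change past the test early. None of the 36 nuclear-encoded subunits of complex I passed, although all 36 had negative values, with a median of -0.11 (camera adjusted p = 3.11e-06, and adjusted p = 0.654 with an estimated correlation). None of the 41 subunits of complexes II to V passed either (median -0.11, camera adjusted p = 2.57e-06, and adjusted p = 0.654 with an estimated correlation). No member of these 2 lists passed when adjusted over the list alone. Without control replicate 3 both medians were -0.03, and camera gave adjusted p of 0.0505 and 0.055. The mitochondrial-encoded mRNAs went the other way, with 6 of 7 positive, none past the test over all genes and 3 up when adjusted over the list alone (median 0.21, camera adjusted p = 0.0109, and adjusted p = 0.568 with an estimated correlation). With cKO replicate 4, whose labels disagree, counted as a control, the mitochondrial-encoded list and complexes II to V did not pass (camera adjusted p = 0.0902 and 0.0708, the latter with a median of -0.06), and the complex I median was -0.05 (camera adjusted p = 0.047). Sarcomere genes, which mark cardiomyocytes, were also lower as a list early, with none of 21 past the test over all genes or adjusted over the list alone (median -0.09, mean 0.05, camera adjusted p = 0.00307, and adjusted p = 0.449 with an estimated correlation). Macrophage markers were higher as a list (median 0.14, camera adjusted p = 0.00332, and adjusted p = 0.645 with an estimated correlation). Of the 20, only Lgals3 was up past the test, with 1 up also when adjusted over the list alone. Late, Lgals3 rose while 14 of the 20 markers fell. The macrophage list did not pass without cKO replicate 2 (median 0.05, camera adjusted p = 0.123).

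Other stress lists held single rises early. Of 17 oxidative stress genes, Hmox1 rose by 0.88 (adjusted p = 0.0149) and Srxn1 by 0.55 (adjusted p = 0.0333) on the log2 scale, and 6 rose when adjusted over the list alone (adjusted p = 0.424 with an estimated correlation). Of 14 immediate early genes, Fosl2 rose by 1.30 (adjusted p = 0.0121), and 9 rose when adjusted over the list alone (adjusted p = 0.424 with an estimated correlation). Of 15 fetal and stress genes of cardiomyocytes, Nmrk2 rose 2.38-fold (adjusted p = 0.0121), and 4 rose when adjusted over the list alone (adjusted p = 0.568 with an estimated correlation). By camera with the preset correlation, the adjusted p was 0.000168 for oxidative stress, 2.46e-06 for immediate early and 0.00307 for fetal genes. By fry it was 0.117, 0.143 and 0.262 in that order. Of 18 mitochondrial chaperones and proteases, the protease gene Lonp1 rose by 0.49 on the log2 scale (adjusted p = 0.0256), 2 rose when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.928, and adjusted p = 0.969 with an estimated correlation). These 5 gene calls and that of Car3 below were each lost without 1 or more of the hearts other than cKO replicate 4 (adjusted p then 0.0517 to 0.121), and the fetal list's camera call was lost without control replicate 3 (adjusted p = 0.055). Car3, which fat cells express strongly, was 9.01-fold higher in cKO hearts (adjusted p = 0.027). The fat cell transcript Adipoq was also higher in 3 of the 4 cKO hearts, at 1.24 to 2.34 CPM, than in any control, where it was at most 0.419 CPM. Cardiac atrial transcripts stood apart in early cKO replicate 2, with 165 CPM of Bmp10 against 0.0593 CPM or less in each of the other early hearts.

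In all, 83 of 13529 tested genes changed early, 70 up and 13 down. All 83 had no overlap between the groups, as did 765 genes (5.7%) among all tested, where chance gives 2.86%. The count was 181 without cKO replicate 4, 46 without cKO replicate 2, 54 without control replicate 2, 46 without control replicate 3 and 45 without control replicate 4, and it was 162 with cKO replicate 4 counted as a control. The preset-correlation camera test called 18 of 36 lists, but none with an estimated correlation, and other splits of the same 8 hearts gave 1 to 23 called lists.

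The late comparison asks what differed once function had failed. The same stress and synthesis genes stood far above control. Psat1 rose from 2.92 ± 0.499 to 417 ± 69 CPM (SD, n = 3; log2 fold change 7.16, SE 0.21, adjusted p = 1.02e-07). Phgdh rose 141-fold (adjusted p = 1.02e-07), Mthfd2 139-fold (adjusted p = 3.97e-08), Asns 197-fold (adjusted p = 1.02e-07) and Slc7a5 51.7-fold (adjusted p = 4.3e-08). Of 29 ATF4 targets, 23 rose and 1 fell, and 23 rose and 2 fell when adjusted over the list alone (adjusted p = 0.465 with an estimated correlation). Of 20 cytosolic aminoacyl-tRNA synthetases, 19 rose, also when adjusted over the list alone (adjusted p = 0.465 with an estimated correlation). Gars rose from 75.6 ± 2.42 to 1170 ± 172 CPM. Of 14 serine, folate and proline genes, 13 rose, also when adjusted over the list alone (adjusted p = 0.448 with an estimated correlation). By camera with the preset correlation, the adjusted p was 1.96e-08 for ATF4 targets, 1.79e-08 for synthetases and 2.9e-07 for serine, folate and proline genes. By fry it was 0.00017, 9.31e-05 and 2.91e-05 in that order.

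Protein turnover and oxidative stress genes rose in the late cKO as well. Of 31 proteasome subunits, 29 rose and none fell, with 30 when adjusted over the list alone (median log2 fold change 0.85, adjusted p = 0.571 with an estimated correlation). Psmd8 rose 5.18-fold (adjusted p = 5.78e-06). Of 18 genes of the oxidative stress response, 13 rose and 1 fell (adjusted p = 0.465 with an estimated correlation). Hmox1 rose 6.50-fold (adjusted p = 1.65e-06) and Nqo1, a quinone reductase, 4.60-fold (adjusted p = 7e-06). Of 20 autophagy and lysosome genes, 13 rose and 2 fell (adjusted p = 0.465 with an estimated correlation), with the lysosomal protease Ctsl up 7.30-fold (adjusted p = 4.3e-07). The cell cycle inhibitor Cdkn1a, a p53 target, rose from 14.2 ± 0.845 to 354 ± 30.9 CPM (adjusted p = 1.02e-07). Of the 16 p53 target and apoptosis genes, 10 rose and 4 fell. The list did not pass camera's test (adjusted p = 0.0994, and 0.465 with an estimated correlation), while fry gave an adjusted p of 0.000172 upward. These counts were equal when adjusted over the list alone for oxidative stress, autophagy and p53 targets. Camera with the preset correlation gave an adjusted p of 3.36e-07 for proteasome, 0.001 for oxidative stress and 0.00581 for autophagy genes. Fry gave 0.00446, 0.000478 and 0.000172 in that order.

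Most respiratory chain subunits were lower late, while genes of glycolysis moved in both directions. Of 36 complex I subunits, 27 fell, also when adjusted over the list alone (median log2 fold change -0.72, camera adjusted p = 0.000585, adjusted p = 0.856 with an estimated correlation, and fry adjusted p = 0.0573). Ndufs1 fell from 732 ± 54.2 to 340 ± 21.2 CPM (adjusted p = 4.61e-05). Of 41 subunits of complexes II to V, 26 fell and 1 rose, with 27 and 1 when adjusted over the list alone (median -0.53, camera adjusted p = 0.000861, adjusted p = 0.856 with an estimated correlation, and fry adjusted p = 0.055). Late cKO replicate 3 stood apart from its group, with a chi-square per gene of 107 and 101 against the other cKO hearts and 21.5 between those. Without it the medians were -1.01 for complex I and -0.80 for complexes II to V. Within cytochrome oxidase, the striated muscle isoform Cox7a1 fell from 672 ± 148 to 30.8 ± 10.7 CPM (adjusted p = 2.82e-06), while Cox6a1 rose from 74.4 ± 10 to 277 ± 101 CPM (adjusted p = 0.00012). Of 20 genes of glycolysis and glucose uptake, 13 rose and 6 fell, also when adjusted over the list alone. Their median was 0.80, and the list did not pass camera's test (adjusted p = 0.0695, and adjusted p = 0.856 with an estimated correlation), while fry gave an adjusted p of 0.00503 upward. Isoforms of enolase moved apart. The muscle form Eno3 fell by 3.66 on the log2 scale (SE 0.18, adjusted p = 7.8e-07) and Eno1 rose by 2.58 (SE 0.17, adjusted p = 3.52e-06). The mitochondrial-encoded share of counts was 13.9% in cKO and 20.8% in control hearts (exact permutation p = 0.1, the smallest possible for n = 3). Among mitochondrial mRNAs, mt-Co1 fell from 70100 ± 9370 to 19900 ± 4650 CPM (adjusted p = 9.41e-05), and mt-Nd1 stood at 29000 ± 4910 and 22000 ± 2210 CPM (adjusted p = 0.0708). Only 7 of the 13 mitochondrial protein-coding genes passed the low-count filter in these comparisons, and the others had at most 399 counts in any library. The highest count of mt-Co1 was 2676984, so the mitochondrial-encoded share above holds almost nothing from those other genes. Whether their reads were lost in counting was not examined here.

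Contractile and calcium-handling genes changed in both directions late. Of 16 fetal and stress genes of cardiomyocytes, 13 rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.448 with an estimated correlation). For this list the adjusted p was 0.000332 by camera with the preset correlation and 0.00017 by fry. Uchl1, a ubiquitin hydrolase, rose from 11.6 ± 2.89 to 516 ± 138 CPM (adjusted p = 6.92e-07), and the growth factor gene Ctgf rose 11.1-fold (adjusted p = 7.82e-07). Of 30 calcium-handling and ion channel genes, 14 fell and 7 rose, also when adjusted over the list alone, and the list did not pass camera's test (adjusted p = 0.115, and adjusted p = 0.856 with an estimated correlation), while fry gave an adjusted p of 0.00446 downward. Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell by 4.21 on the log2 scale (SE 0.14, adjusted p = 1.59e-07), the potassium channel genes Kcnd2 by 4.34 (SE 0.20) and Kcnip2 by 2.94 (SE 0.15), and the gap junction gene Gja1 by 1.83 (SE 0.17, adjusted p = 1.84e-05). Of 21 sarcomere genes, 8 rose and 5 fell, and the list's median was 0.14 while its mean was -0.19 (camera adjusted p = 0.8, adjusted p = 0.962 with an estimated correlation, and fry adjusted p = 0.883). Myoglobin (Mb) fell from 12100 ± 1890 to 1970 ± 332 CPM (adjusted p = 5.18e-06). The matrix genes Lox, Tgfb2 and Eln rose 21.1-fold, 11.6-fold and 5.74-fold, and the 34-gene matrix list had 17 rises and 8 falls (camera adjusted p = 0.105, adjusted p = 0.871 with an estimated correlation, and fry adjusted p = 0.0525). For the sarcomere and matrix lists the counts were equal when adjusted over the list alone.

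Endothelial, fibroblast and macrophage markers were lower in late cKO hearts, and red blood cell transcripts were higher. Of 17 endothelial markers, 15 fell and none rose, also when adjusted over the list alone (median log2 fold change -1.14, adjusted p = 0.448 with an estimated correlation), with Kdr down from 224 ± 30.9 to 62.2 ± 9.66 CPM. Of 15 fibroblast markers, 11 fell and 2 rose (median -1.59, adjusted p = 0.487 with an estimated correlation), and of 20 macrophage markers, 14 fell and 2 rose (median -0.64, adjusted p = 0.511 with an estimated correlation). The rising macrophage markers were Lgals3, which rose 128-fold (adjusted p = 1.5e-07), and Gpnmb, which rose 4.96-fold. All 7 tested erythroid transcripts rose (median 2.34, adjusted p = 0.511 with an estimated correlation), including Hbb-bs from 27.5 ± 7.3 to 140 ± 46.3 CPM. All 20 interferon response genes fell (median -2.23, camera adjusted p = 1.79e-08, and adjusted p = 0.138 with an estimated correlation), with Rsad2 down from 23.4 ± 3.15 to 2.69 ± 0.319 CPM. The correlation estimated for this list was 0.01, the preset value, so correlation does not account for the gap between its camera values. Of 14 cytokine and chemokine genes, 11 fell and Lcn2 rose 140-fold (list adjusted p = 0.448 with an estimated correlation). Of 17 cell cycle genes, 12 fell and 3 rose (adjusted p = 0.511 with an estimated correlation), with Mki67 down from 7.29 ± 1.83 to 1.20 ± 0.228 CPM. Adjusted over the list alone, the counts of these fibroblast, macrophage, erythroid, interferon, cytokine and cell cycle lists were equal. Camera's adjusted p with the preset correlation was 0.000249 for endothelial, 0.00446 for fibroblast and 0.0237 for macrophage markers. It was 0.00289 for the erythroid, 0.00167 for the cytokine and 0.011 for the cell cycle list. Fry gave adjusted p of 0.000227, 0.000478, 0.00931, 0.00446, 0.000229 and 0.00244 for these lists in that order. Lists of 4 other tissues or cell types did not pass camera's test. Lymphocyte and neutrophil markers had 1 rise and 3 falls among 5, also when adjusted over the list alone (camera adjusted p = 0.438, adjusted p = 0.803 with an estimated correlation, and fry adjusted p = 0.000422 downward), and adipocyte markers 1 and 1 among 6, or 1 and 0 when adjusted over the list alone (camera adjusted p = 0.688, adjusted p = 0.906 with an estimated correlation, and fry adjusted p = 0.643). Skeletal muscle markers had 2 rises and 3 falls among 6, also when adjusted over the list alone, with a median of -0.35 and a mean of 0.29 (camera adjusted p = 0.956, adjusted p = 0.967 with an estimated correlation, and fry adjusted p = 0.439). Atrial and valve markers had 1 rise and 2 falls among 8, or 1 and 1 when adjusted over the list alone, with a median of 0.26 and a mean of -0.47 (camera adjusted p = 0.8, adjusted p = 0.967 with an estimated correlation, and fry adjusted p = 0.76). Of 18 circadian clock genes, 7 rose and 9 fell, also when adjusted over the list alone, and the list did not pass camera's test (adjusted p = 0.61, adjusted p = 0.898 with an estimated correlation, and fry adjusted p = 0.0154 downward). The clock output gene Dbp fell from 199 ± 19 to 10 ± 1.61 CPM, and its regulator Arntl rose from 1.79 ± 0.334 to 14.1 ± 2.07 CPM. These genes also differed within a group, with 57.7 CPM of Dbp and 16 of Arntl in early cKO replicate 2. Early cKO replicate 4 held 176 CPM of Dbp and 2.13 of Arntl. The time of day at which hearts were taken was not examined here.

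**Figure D2:**
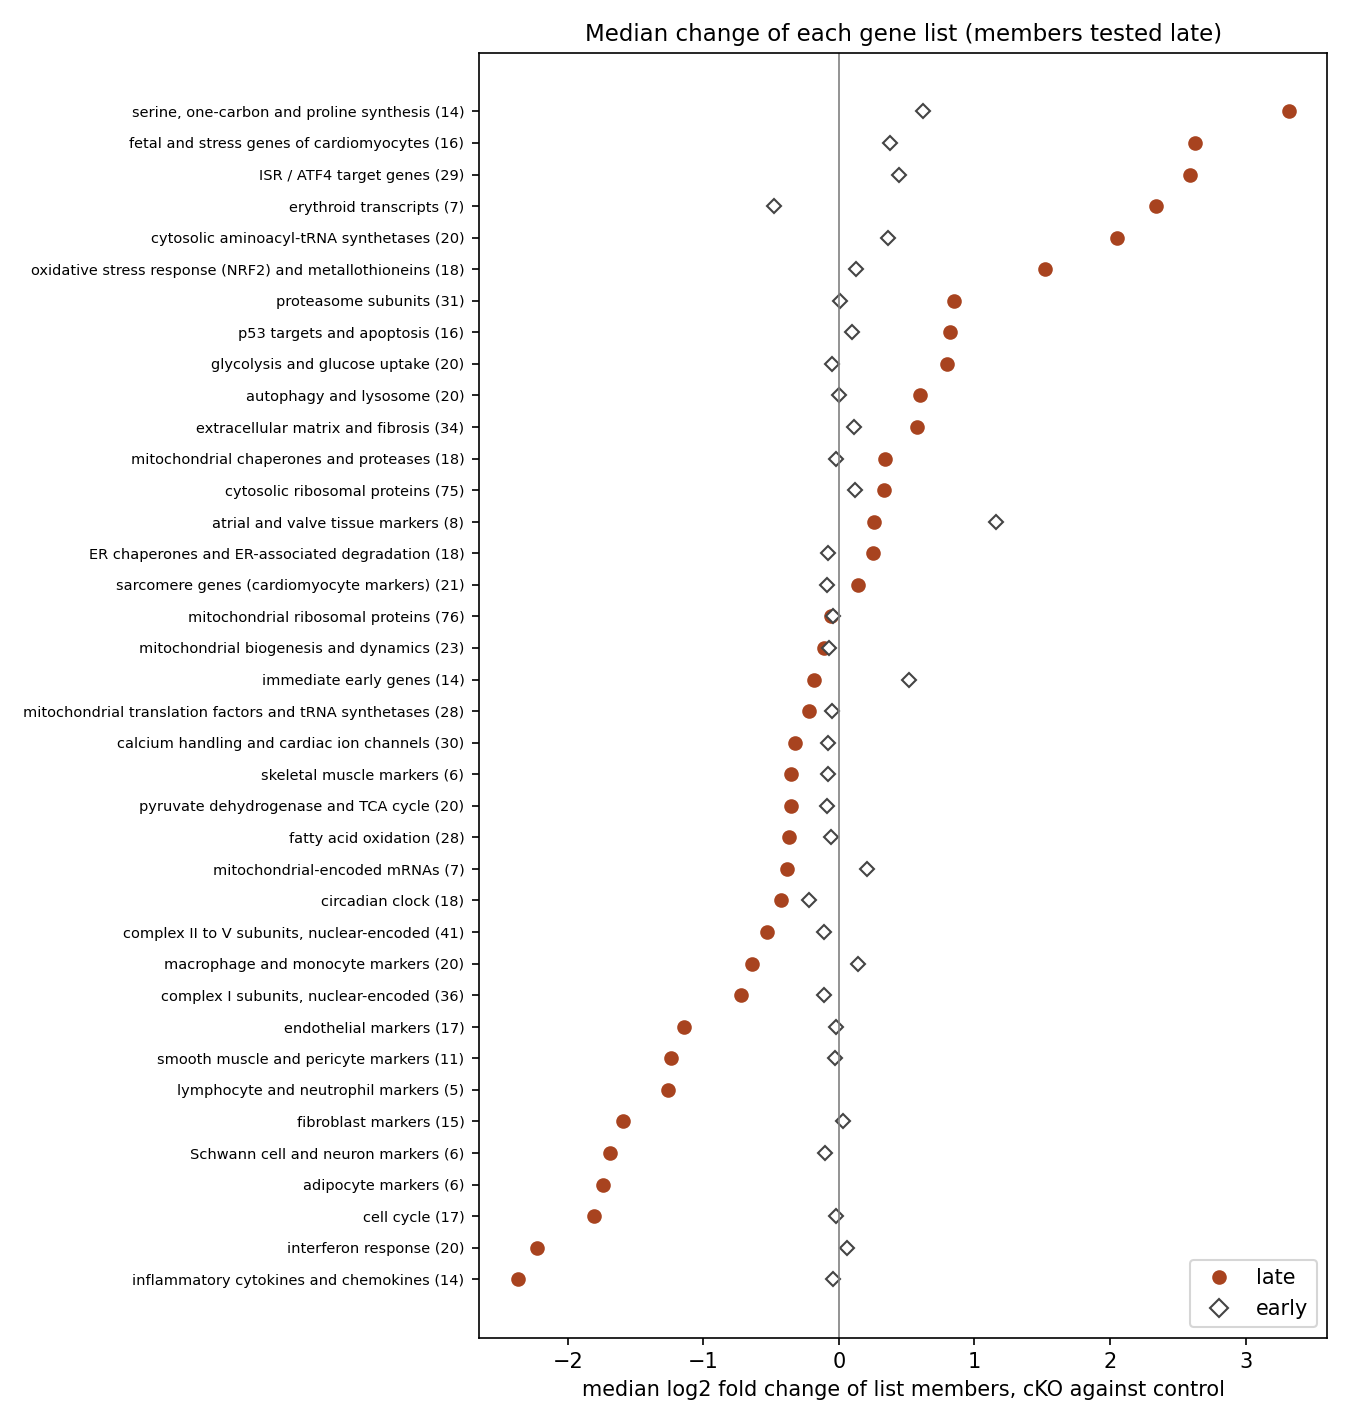
Median log2 fold change of each gene list, cKO against control, early (open diamonds) and late (filled circles), with the number of members tested late in brackets. Late medians ran from -2.37 for cytokines to 3.32 for serine, folate and proline synthesis.

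Several of the largest late changes were in genes almost silent in 1 group. Vmn2r3, of the vomeronasal receptor family, whose near-identical members can share reads, had 7337 counts in the cKO group and 1 in controls, a ratio of 7210 (95% counting interval 1290 to 285000). B4galnt2, a glycosyltransferase gene, was at least 496-fold higher, Fibcd1 at least 302-fold and Dthd1 at least 163-fold, since all 3 controls held no count. Cyb5r2 had a ratio of 887 (95% counting interval 303 to 4310), and Adm2, which encodes a peptide hormone, of 745 (254 to 3610). Ostn, which encodes a secreted muscle peptide, rose from 0.127 ± 0.0887 to 88.8 ± 23.4 CPM and Akr1b7 from 0.053 ± 0.0387 to 31.9 ± 3.97 CPM. Their log2 fold changes were 9.42 and 9.15 with all hearts, and 10.12 and 9.86 without late control replicate 1. Retnla, a secreted protein of alternatively activated macrophages, was at least 144-fold lower. The carboxylesterase Ces1d fell from 179 ± 52.1 to 0.739 ± 0.281 CPM (log2 fold change -7.91, adjusted p = 3.37e-07), Itgb6 from 13.8 ± 0.748 to 0.143 ± 0.00676 CPM and Cenpf from 32.5 ± 10.8 to 0.283 ± 0.221 CPM. Esr1, the estrogen receptor gene on chromosome 10 from 4611593 to 5005614, fell from 4150 ± 668 to 27.9 ± 28.1 CPM (log2 fold change -7.22, SE 0.74, adjusted p = 3.64e-05). Late cKO replicate 1 held 60.1 CPM against 8.90 and 14.6 CPM in the other cKO hearts, and without it the change was -8.46. Early, Esr1 was at 2476 ± 456 CPM in cKO and 3486 ± 433 CPM in control hearts, lower in every cKO heart than in any control (exact permutation p = 0.0286, the smallest possible for n = 4; edgeR adjusted p = 0.138). Its reads can also come from the transgene, which fuses Cre to mutated estrogen receptor domains.

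In all, 9714 of 14942 tested genes changed late, 4757 up and 4957 down, of which 2235 rose and 3045 fell by a log2 fold change of at least 1 in size. The groups did not overlap for 69.8% of tested genes, where chance gives 10%. Leaving out each heart in turn gave 8539 to 10718 calls. The preset-correlation camera test called 20 of 38 lists, none with an estimated correlation. Another split of the same 6 hearts also gave 20 called lists with the preset correlation.

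The early and late comparisons share no library. Of 83 genes changed early, 68 were also called late in the same direction, 59 up and 9 down, where 21.7 and 4.49 would be shared by independent lists of these sizes. Another 4 were called in opposite directions, Cecr2, Car3, Sema6a and Hlx, which were named here after their values were seen. Car3 was found with fat cell transcripts late as well. Late control replicates 2 and 3 held 15.9 and 10.7 CPM of Car3, 1.51 and 1.02 CPM of Adipoq and 11.6 and 5.67 CPM of Cfd, against 0.586, 0.13 and 0.423 CPM in control replicate 1. Of all 83, 72 had the same sign late. Across the 13485 genes tested at both times, which are not independent replicates, the log2 fold changes had a Pearson r of 0.24 and a Spearman rho of 0.21. The shared count was 133 without early cKO replicate 4, 41 without early cKO replicate 2, 38 without early control replicate 3 and 42 without early control replicate 4.

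**Figure D3:**
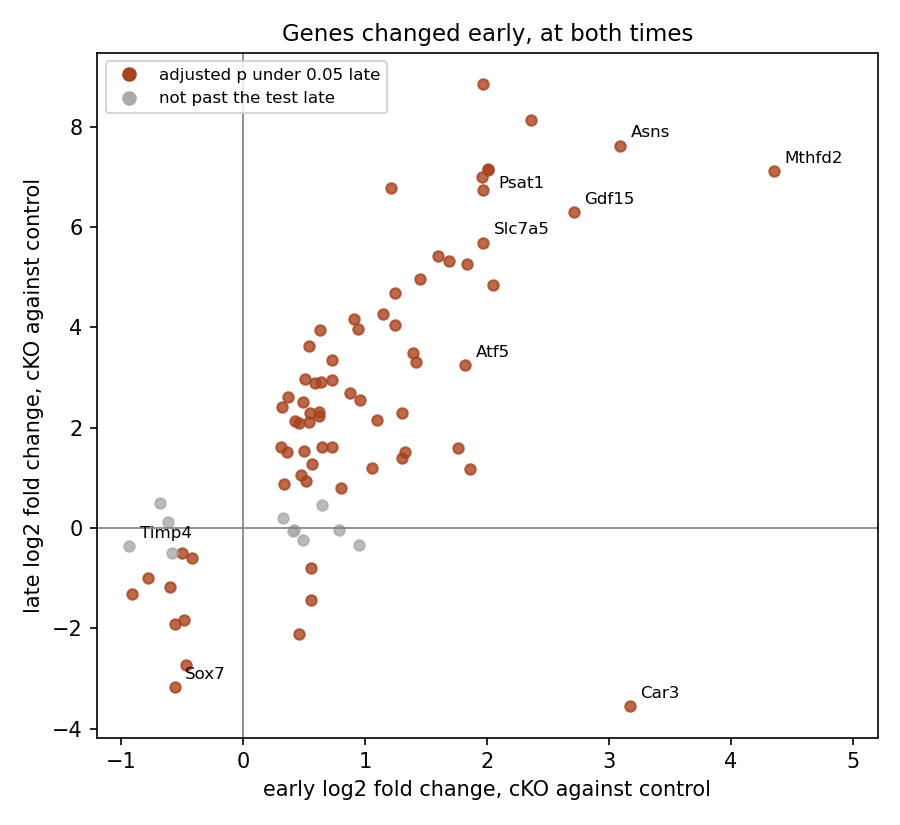
Log2 fold change early (x axis) and late (y axis) of the 83 genes called early, with each point a gene, coloured where the late change also passed the test. Mthfd2 stood at 4.35 early and 7.12 late, and Car3 at 3.17 early and -3.56 late.

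The change in expression differed between the times for 8903 of 14555 genes by the genotype-by-time test. Fam210a fell by 0.70 more on the log2 scale late than early (SE 0.11, adjusted p = 3.92e-05). The largest positive differences were Ptprt (7.17 on the log2 scale, SE 1.32), Cyb5r2 (6.91, SE 2.11), Acox2 (6.88, SE 0.52), Akr1b7 (6.87, SE 1.33) and Lcn2 (6.86, SE 0.43). Their order is not resolved, since Ptprt was 10.26 without late control replicate 2 and Akr1b7 was 5.89 without early control replicate 4 and 7.54 without late control replicate 1. The largest negative ones included Retnla (-9.03, SE 1.11). Where a group held almost no counts, as for Cyb5r2 and Retnla, the fitted size depends on the fitting method and is no bound. The call of Cyb5r2 was lost without early control replicate 1 (6.44, adjusted p = 0.0716) or 4 (6.44, adjusted p = 0.0718). Time and sequencing table are the same split, so the test compares the changes within each table and not the levels.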

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

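The tests on early cKO replicate 4, on Esr1 and on cell type markers below were chosen after the values had been seen. The regroupings of the hearts were planned.

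Early, only the real split among the 35 splits of the 8 hearts gave as many called genes (83, against at most 4 in any other). A share of 1 in 35 is the smallest these splits can give, so chance is unlikely for the count but not excluded. The number of lists called is another matter. As many lists as the 18 of the real split were called in 4 of the 35 splits, with up to 23 in another split, so chance cannot be excluded for that number. Late, 10 splits of 6 hearts are too few for a share under 0.05. The real split gave 9714 genes, with 0 in the highest other split, and 20 lists, with 20 in the highest other split (1 and 2 splits reached the real values). The 68 genes called alike at both times were reached by 1 of 35 early splits, with 3 in the highest other. No other early split called more than 4 genes, so none was able to reach 68, and these splits do not test the overlap.

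The change differed between times for 8903 genes, and 2 of 100 drawn regroupings gave as many, with 8996 in the highest other. That other regrouping kept the real late groups and shuffled only the early ones, while regroupings with other late groups gave at most 1 call. The count therefore follows the late groups, of which there are only 10 splits. These are too few for a share under 0.05, although fewer than 5% of the drawn regroupings gave as many. The differences were 7.17 for Ptprt, 6.91 for Cyb5r2, 6.88 for Acox2, 6.87 for Akr1b7, 6.86 for Lcn2, -9.03 for Retnla, -8.27 for RP24-79E2.2, -7.90 for RP23-464K22.1 and -0.70 for Fam210a. Ptprt was 10.26 without late control replicate 2, Akr1b7 was 5.89 without early control replicate 4 and 7.54 without late control replicate 1, and RP23-464K22.1 was -9.42 without late cKO replicate 3. Of the 20 genes named for the largest early changes, 14 had a change that differed between times. Bmp10, an atrial transcript, differed by -16.91, which rested on early cKO replicate 2 (2846 counts) and late control replicate 3 (3468 counts). It was -7.56 without that control (adjusted p = 0.677) and -2.8 with limma-voom (adjusted p = 0.638). The adjusted p ran from 3.24e-11 to 0.677 over all alternatives with a value.

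In 6 of 78 group values of the early hearts a single heart stood apart from the other 3 by Dixon's test at its 95% critical value, which by design marks about 1 in 20 groups by chance. Early cKO replicate 4 was low for Iars (96.8 CPM against 108 to 109) and Hmox1 (10.0 against 15.6 to 16.7). Control replicate 1 was low for Timp4 (31.5 CPM against 39.3 to 40.3) and high for Atf4 (67.2 against 59.7 to 60.4). Control replicate 3 was low for Banp (13.1 CPM against 14.9 to 15.1) and high for Rpl3 (92.9 against 87.9 to 88.2).

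Early cKO replicate 4, whose labels disagree, stood between the groups. On the 181 genes called without it, its median position was 0.39 on a scale where the control mean is 0 and the mean of the other cKO hearts is 1 (interquartile range over genes 0.14 to 0.60). Controls left out in the same way lay at 0.03 to 0.08, so a mislabelled control heart is argued against. The other cKO hearts lay at 0.85 to 1.22, which a knockout heart with a smaller response would allow. Why its response may be smaller was not tested.

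The near loss of Esr1 reads in late cKO hearts, which were already lower early (2476 against 3486 CPM, exact permutation p = 0.0286, the smallest possible), was weighed against 4 explanations. Fewer cardiomyocyte transcripts would lower sarcomere genes too, but their median log2 change was 0.14. Lower output of the Myh6 promoter would lower Myh6 mRNA, which changed by 0.19 (SE 0.15), although the endogenous gene need not track a transgene. Mhrt, a noncoding RNA of the same myosin locus, was lower late. It stood at 8.13 to 10.7 CPM in cKO hearts and 93.8 to 119 CPM in controls, so lower promoter output stays open. Loss of non-myocytes that express the endogenous gene would need markers to fall by a similar size, and the lower of the fibroblast and endothelial medians was -1.59 against -7.22 for Esr1 (-8.46 without late cKO replicate 1). Loss or silencing of the Mer-Cre-Mer transgene may account for a level of 0.672% of control, which rests on late cKO replicate 1 (60.1 CPM against 8.90 and 14.6 CPM), but the tables hold no row for Cre, so it stays open.

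Markers of several other cell types were lower late in the cKO, while adipocyte and lymphocyte lists did not pass camera's test (adjusted p = 0.688 and 0.438, adjusted p = 0.906 and 0.803 with an estimated correlation, and fry adjusted p = 0.643 and 0.000422, both downward). A lower share of every other cell type is argued against, since the medians of 8 lists, with red blood cells rising, differed by more than shuffled genes did (permutation p = 0.00049). Among only the 5 cell types of the heart wall, a set formed after the medians were seen, no such difference was detected (permutation p = 0.102) and 85.5% of 69 markers were negative, so a lower share of these cells may contribute. Interferon genes fell further than those markers (median -2.23 against -1.15, permutation p = 0.0001), so such a share would not account for all of their fall. Genes were treated as independent in these permutations, and a change within the cells stays open and untested.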

How the results depend on the processing

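The alternative chosen after seeing the data left out the hearts with the most atrial transcripts. No scaling moved the median of all genes by over 0.1. Each scaling sets most genes near no change, so that value was fixed in advance and tests nothing. Late, 65% of tested genes were called, so late rises and falls are relative to that assumption. The late count and the count of genes that differed between times stayed within 1.5 times their values under every alternative run. The early count of 83 (84.3% up) did not. It was 388 with no low-count filter (67.0% up), 176 with DESeq2 (70.5% up), 162 with early cKO replicate 4 counted as control (59.9% up) and 46 without the atrial-rich heart. Leaving out 1 heart gave 45 to 181 calls, and 40 to 79 of the 83 genes kept their call. The 68 genes called alike at both times became 24 at an adjusted p under 0.01, 127 with DESeq2, 109 with early cKO replicate 4 as control, 39 without the atrial-rich hearts and 38 to 133 when 1 heart was left out. With an estimated correlation 0 lists were called early and 0 late by camera, while fry called 3 and 26. The late interferon call was lost although its estimated correlation equalled the preset 0.01, so lost calls do not measure correlation alone. Fam210a early passed the test only with DESeq2 (log2 fold change -0.23, adjusted p = 0.0456, with 0.0456 to 0.499 over its alternatives). Bmp10 late ranged from -6.55 to 3.41 when 1 heart was left out, against -5.98 with all hearts. It turned to 3.41 without late control replicate 3, which held 3468 Bmp10 counts. Without the atrial-rich hearts, which include that control, Bmp10 turned to 3.57. Its late call was also lost with limma-voom (-0.18, adjusted p = 0.958) and without late cKO replicate 1 (-5.82, adjusted p = 0.0795) or 2 (-5.88, adjusted p = 0.0917). Its adjusted p ran from 1.93e-05 to 0.958 over all alternatives with a value. The cause of the other shifts was not tested. Among the named genes and the called lists, 218 values fell short of the threshold in an alternative and 3542 kept their side.

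Hearts with the same replicate number did not deviate together (correlations of deviations -0.09 to -0.04 early and -0.41 to -0.06 late). Hearts with different numbers were not compared in this way, so a pairing was not seen but is not excluded. The replicate block gave 78 early calls, 8374 late calls, 8012 genes that differed between times, 17 early and 18 late lists and 64 shared genes, and Fam210a changes of -0.23 early and -0.94 late. The block kept 61 of the 83 early calls, 8365 of the 9714 late calls and 7981 of the 8903 calls between times. Among only the named genes and the called lists, 12 gene calls and 3 list calls were lost with it. That of Bmp10 late was among them (-3.19, adjusted p = 0.266). In simulations of the late design with 200 changed genes, 16% of 1.5-fold changes were recovered. That share holds for few changed genes and does not carry over to data with 9714 calls.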

Other observations

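Mitochondrial RNAs moved apart from each other in late cKO hearts. These genes were chosen after their values were seen. The ribosomal RNA mt-Rnr2 rose from 5080 ± 416 to 9090 ± 2260 CPM (log2 fold change 0.84, edgeR adjusted p = 0.00385), while mt-Rnr1 fell by 0.62 on the log2 scale (adjusted p = 0.00206). The tRNA gene mt-Tp rose by 3.21 (SE 0.27, adjusted p = 1.22e-05), mt-Tt by 2.13 (SE 0.28) and mt-Tq by 3.56 (SE 0.48), each from under 3 CPM in controls. The tRNA gene mt-Ti, more abundant in controls, fell from 21.7 ± 5.6 to 4.37 ± 1.19 CPM (adjusted p = 5.63e-05), and mt-Tm stood at 24.7 ± 2.78 and 18.3 ± 11.6 CPM in control and cKO hearts (adjusted p = 0.308). Among mRNAs, mt-Co1 fell by 1.82 on the log2 scale and mt-Nd4 by 0.79. The mRNA mt-Nd2 stood at 20400 ± 4870 CPM in cKO and 15700 ± 1250 CPM in control hearts (adjusted p = 0.116). Poly-A selection, the handling of reads that match more than 1 place, and whether counts at tRNA genes come from mature tRNAs were not examined here.

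Among lists not described above, the late nuclear-encoded mitochondrial ribosomal proteins had 17 rises and 18 falls (16 and 17 when adjusted over the list alone, and adjusted p = 0.967 with an estimated correlation). The genes of mitochondrial translation had 10 falls and 2 rises (adjusted p = 0.856 with an estimated correlation). Tufm, a mitochondrial elongation factor, fell from 159 ± 14.9 to 50.5 ± 7.01 CPM (adjusted p = 1.06e-05). Of 28 fatty acid oxidation genes, 14 fell and 5 rose late (adjusted p = 0.871 with an estimated correlation). Of 20 genes of the pyruvate dehydrogenase and TCA cycle list, 11 fell and 1 rose, with 11 and 0 when adjusted over the list alone (adjusted p = 0.856 with an estimated correlation). None of these 4 lists passed camera's test with the preset correlation either, with adjusted p from 0.0646 to 0.688. By fry the adjusted p was 0.649 for mitochondrial ribosomal proteins, and downward it was 0.0239 for mitochondrial translation, 0.0409 for fatty acid oxidation and 0.0231 for the TCA cycle list. Of 11 smooth muscle and pericyte markers, 9 fell and 2 rose (adjusted p = 0.511 with an estimated correlation), with Acta2 up 6.97-fold (adjusted p = 1.16e-05). Of 6 Schwann cell and neuron markers, 5 fell (adjusted p = 0.487 with an estimated correlation). By camera with the preset correlation, the adjusted p was 0.0497 for the smooth muscle list and 0.00761 for the Schwann cell list. By fry it was 0.0027 and 0.00084. The smooth muscle list passed camera's test in 4 of 10 alternatives. For the lists given here without such counts, the counts were equal when adjusted over the list alone.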
